A study of Homo sapiens with 4 samples.

How the data were processed

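RNA from K562 cells, a human leukaemia line of erythroid and megakaryocytic character, was sequenced in 4 libraries. 2 were labelled control and 2 were labelled FAM122A knockout. Per the labels' protocols, RNA was extracted with Trizol and made into libraries with an Illumina TruSeq RNA kit; the labels do not say whether the kit kept the strand. The knockout method, the number of clones and whether the replicates came from separate cultures are not given in the sources used here, so p-values measure only the spread between these libraries, which may be technical.

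The deposited table lists 13716 genes with 1 value per library, a gene type, a symbol and a chromosome band. FastQC, STAR 2.4.2a, edgeR and the build hg19 are named in the submitters' processing notes without a role or an order. The read counter, the gene annotation and the scaling are not given in the sources used here. The unit was therefore read from the values: the deposited values are a scaled signal per gene of the counts-per-million kind, that is, read counts divided by 1 factor per library and rounded to 3 decimals. The columns sum to 976889 and 966201 in the control libraries and to 1025725 and 1026004 in the knockout libraries, so the factor is not the plain library total. The lowest maximum of any listed gene over the libraries was 1, so genes under that level in all 4 libraries are not listed. The table holds no fold change or p-value, so the planned comparison with a deposited test was not made.

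Each column rises in whole steps of 1 value, taken here as what 1 read is worth. All values (100% in each library) lay within 0.00076 of a whole number of steps. The steps were 0.0492 and 0.0593 in the control libraries and 0.0189 and 0.0165 in the knockout libraries. If each step is 1 read, the listed genes hold an estimated 1.99e+07 and 1.63e+07 reads in the control libraries and 5.43e+07 and 6.20e+07 in the knockout libraries, 3.22 times as many on average. These steps were used to describe depth and to thin reads, and no count model was fitted to them, because the deposited values are scaled and the reads are inferred. Over genes with at least 50 reads in both replicates together, the mean chi-square per gene between replicates was 2.04 in the control group (12759 genes) and 5.05 in the knockout group (13687 genes), where 1 is sampling noise alone, so no library was a copy of another. The excess of chi-square over 1 grows with depth at the same relative spread, so these values do not compare the spread of the groups. Pearson's r of log2 values across genes was 0.997 between the control libraries, 0.998 between the knockout libraries and 0.993 to 0.994 between groups.

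The count test planned before the data were examined was replaced by the test planned for normalized values: limma 3.58.1 (R 4.3.3) with a mean-dependent prior (trend) on log2(value + 1), two-sided, for the 13249 genes whose mean over the 4 libraries was at least 1. 467 genes were left out. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. With 2 residual degrees of freedom the estimate of spread rested on a prior worth 16.3. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. 28 gene lists were fixed before the data were examined; the 26 with at least 5 measured members were tested against all other genes with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 26 lists. Camera with an estimated correlation and fry were alternatives.

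GC content and length came from the longest transcript of each gene in GENCODE 29, matched by Ensembl identifier, for 12878 of the 13249 genes (97.2%) and 97.9% of the called genes. GENCODE 29 uses another build than hg19, so it supplied only these properties and the overlap of gene models, and no coordinates are given. Each library's trend with GC content and log2 length was fitted by loess (span 0.3) and subtracted as an alternative, chosen after seeing the data. The removal also centres each library, so it was repeated with each library's median put back. This removal would also remove any effect of the knockout that follows GC content. Other alternatives planned before the data were examined were the replicate number as a block, median-of-ratios scaling, library totals, quantile normalization, other filters (none, or a mean of at least 5), a pseudocount of 0.1, stricter thresholds and leaving out each library. Thinning of the knockout reads to the mean control depth, weights for each group, the trend removed with an absolute log2 change of at least 0.5 and the trend removed with library medians kept were added after seeing the data. Simulated tables of 13249 genes with 200 changed took their control means and depths from these libraries. Changed genes were drawn from those with a mean of at least 5 and a known GC content. Beside sampling noise, the coefficient of variation was set at 0.04, independent between genes. The test recovered 32% of changes of 0.25 and 100% of changes of 0.5, 1 and 2 on the log2 scale. It called 5 unchanged genes. With a GC trend added to the knockout libraries it called 1168 unchanged genes, of which 65.2% were called up, and 10 after the trend was removed. Real spread may be larger or shared between genes, so these results do not give the power or false calls in the real data.

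Genes are named by a rule fixed before the data were examined. It takes FAM122A and PIP5K1B; the 10 largest rises and 10 largest falls among called genes with a mean of at least 5, a symbol and no overlap between the groups, leaving out pseudogenes; 17 erythroid and related genes whatever their result; up to 4 members with the smallest p of each list; and the 5 smallest p in each direction. Some genes that the rule takes are not reported here, and the named-gene totals leave them out. Where 5 or fewer members of a list passed in a direction, or were left over, those outside the rule are named as well. They were chosen after their values were seen: HBD, NDUFB5, SKIL, FAM122B, MASTL, KIF20A, AURKB, MCM5, MCM7, GINS4, POLA1, AEN, SESN2, DDB2, XPC, FOS, JUNB, NR4A1, CTSL, BCL2L1, BID and BAD. HBA1 and HBA2, HBG1 and HBG2, SLX1B and its copy, HIST2H4B and its copy, RN7SL1, and genes that overlap others (MSH5-SAPCD1, MSANTD3-TMEFF1, the antisense genes) are uncertain, since the counting of shared reads and the use of strand are not given in the sources used here. The chromosome bands are those of the deposited table. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.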

Results

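Gene expression was measured by RNA sequencing in K562 cells labelled FAM122A knockout and in K562 cells labelled control (NC), with 2 libraries in each group. FAM122A encodes an inhibitor of the phosphatase PP2A. The comparison asks how the transcriptome of this erythroid-like leukaemia line differs when FAM122A is disrupted. Values are a scaled counts-per-million signal, and changes are log2(value + 1) of the knockout group minus the control group with their standard error (SE). The knockout libraries were the deeper ones, with an estimated 5.43e+07 and 6.20e+07 reads in the listed genes against 1.99e+07 and 1.63e+07 in the control libraries, if the smallest step of each column is 1 read.

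The targeted gene, FAM122A at 9q21.11, stood at 9.78 and 9.26 in the control libraries and at 10.6 and 9.15 in the libraries labelled knockout. The change was 0.04 (SE 0.10, n = 2 per group, limma adjusted p = 0.78). A frame-shifting edit need not lower the mRNA, so this level does not check the labels, and "knockout" below stands for the libraries labelled knockout. FAM122A is a single-exon gene inside an intron of PIP5K1B on the same strand, with 0 shared exon bases in GENCODE 29. PIP5K1B stood at 10.2 ± 0.055 (SD, n = 2) in control and 8.84 ± 0.763 in knockout libraries (change -0.19, SE 0.10, limma adjusted p = 0.16). Of the 9 genes listed beforehand as neighbours on 9q21, 4 were measured, none passed over all genes or adjusted over the list alone, and their median change was 0. PTAR1 was 97.0 ± 0.362 in control and 102 ± 7.04 in knockout libraries (limma adjusted p = 0.258). It passed upward without knockout replicate 1 (0.141) and with the GC trend removed (0.172). C9orf135 at 9q21.12, which was not on that list, rose by 1.45 (SE 0.12, limma adjusted p = 1.08e-07).

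Several haemoglobin genes were among the genes with the largest rises. HBZ, the embryonic zeta globin, rose from 249 ± 4.82 to 680 ± 27.1 (SD, n = 2), a log2 change of 1.44 (SE 0.03, limma adjusted p = 2.06e-15). HBA1 rose from 390 ± 0.711 to 790 ± 17 (1.01, SE 0.03, limma adjusted p = 1.3e-13) and HBA2 from 55.9 ± 4.56 to 136 ± 1.09 (1.27, SE 0.05, limma adjusted p = 2.93e-12). How reads common to these near-identical alpha globin genes were counted is not given in the sources used here, and their summed value rose by 1.05. The fetal gamma globins HBG1 and HBG2, also near-identical, rose from 564 ± 5.92 to 930 ± 3.13 and from 1600 ± 3.18 to 2630 ± 56.1, by 0.72 and 0.71 (SE 0.03 each), and their sum rose by 0.71. HBB, the adult beta globin, rose from 6.85 ± 0.878 to 29.2 ± 1.79 (1.95, SE 0.09, limma adjusted p = 4.23e-11). The embryonic HBE1 rose less, from 96.6 ± 0.73 to 116 ± 6.93 (0.26, SE 0.04, limma adjusted p = 0.000184). Of the 10 measured members of the globin list 9 rose, over all genes and adjusted over the list alone, and HBD did not pass (1.15 in control and 1.65 in knockout libraries). All globin genes of the list together took 0.31% of the listed values in each control library and 0.52% in each knockout library.

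**Figure D1:**
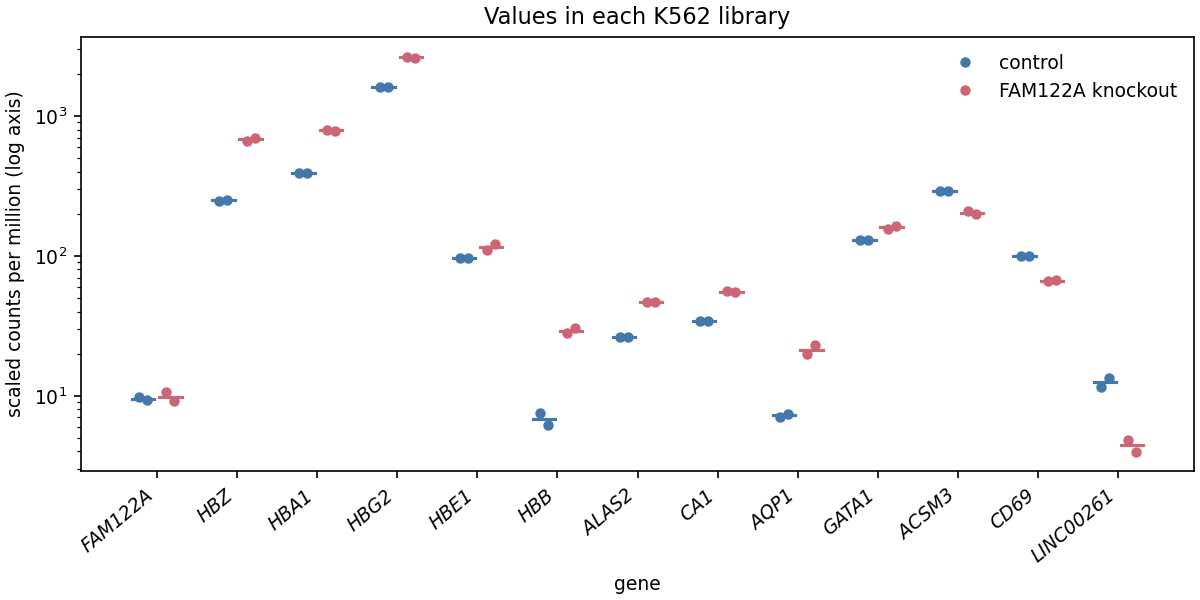
Scaled counts-per-million signal (log axis) of 13 genes in each library, with the 2 control libraries in blue and the 2 FAM122A knockout libraries in red; points are libraries and bars are group means. The globin genes, ALAS2, CA1, AQP1 and GATA1 lie higher in both knockout libraries than in both control libraries, ACSM3, CD69 and LINC00261 lie lower, and FAM122A overlaps between the groups (9.26 to 9.78 against 9.15 to 10.6).

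Genes of haem synthesis and iron handling rose together with the globins. 16 of 24 members rose and 0 fell, with the same counts adjusted over the list alone, and their median change was 0.2 (camera adjusted p = 3.12e-07 and adjusted p = 0.187 with an estimated correlation). ALAS2, the erythroid enzyme that starts haem synthesis, rose from 26.4 ± 0.0368 to 46.8 ± 0.18 (0.80, SE 0.06, limma adjusted p = 1.19e-08). The mitochondrial carriers SLC25A39 and SLC25A37 (mitoferrin) rose by 0.46 (SE 0.03) and 0.44 (SE 0.04), the haem pathway enzyme CPOX by 0.39 (SE 0.03) and the transferrin receptor TFRC by 0.31 (SE 0.03), from 814 ± 30.9 to 1010 ± 7.22. The globin list as a whole had a median change of 0.72 (camera adjusted p = 1.46e-13 and adjusted p = 0.187 with an estimated correlation).

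Among genes of the red cell membrane and surface 17 of 26 rose and 0 fell, the same counts adjusted over the list alone (median 0.22, camera adjusted p = 9.75e-07 and adjusted p = 0.187 with an estimated correlation). The water channel AQP1 rose from 7.25 ± 0.239 to 21.4 ± 2.2 (1.44, SE 0.09, limma adjusted p = 4.88e-09) and the carbonic anhydrase CA1 from 34.2 ± 0.36 to 55.4 ± 0.447 (0.68, SE 0.05, limma adjusted p = 3.37e-08). The glucose transporter SLC2A1 rose by 0.35 (SE 0.04) and the glycophorin GYPC by 0.32 (SE 0.03).

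Erythroid transcription and signalling genes moved by less. 13 of 24 rose and 1 fell (15 and 2 adjusted over the list alone), with a median of 0.13 (camera adjusted p = 0.00244 and adjusted p = 0.348 with an estimated correlation). The list lost its call with the GC trend removed (6 rose, 2 fell, median 0.04, camera adjusted p = 0.187). GATA1, the master regulator of the erythroid lineage, rose from 129 ± 0.33 to 160 ± 4.97 (0.30, SE 0.04, limma adjusted p = 9.92e-06), and by 0.13 with the GC trend removed. KLF1, a transcription factor of globin genes, rose from 55.4 ± 3.89 to 69.1 ± 3.32 (0.32, SE 0.05, limma adjusted p = 0.000192), a call that ended with the trend removed (0.08, limma adjusted p = 0.28). The kinase PIM1 and the factor LYL1 rose by 0.28 (SE 0.03) and 0.34 (SE 0.05), and MYB, a factor of progenitor cells, fell from 180 ± 6.5 to 153 ± 0.26 (-0.24, SE 0.04, limma adjusted p = 0.000103). EPOR, the erythropoietin receptor, did not pass (8.63 ± 0.384 and 9.77 ± 0.923, limma adjusted p = 0.248).

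Of 30 genes listed as activated by GATA1 22 rose and 0 fell (23 and 0 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 1.22e-13 and adjusted p = 0.187 with an estimated correlation). 29 of these 30 also belong to an erythroid list above, so this count is not independent of them. Of 13 measured genes listed as repressed by GATA1 3 rose and 2 fell (3 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.772). CCND2, a D-type cyclin, rose by 0.35 (SE 0.04), LYL1 as above, and GATA2 by 0.25 (SE 0.04; from 143 ± 0.221 to 171 ± 6.99), a call that ended with the trend removed (0.09, limma adjusted p = 0.0854). MYB and SKIL fell. KIT, a progenitor receptor, was 18.6 ± 0.348 in control and 16.0 ± 1.08 in knockout libraries (limma adjusted p = 0.0571) and passed downward under library totals (-0.276), median-of-ratios scaling (-0.228), thinned reads (-0.248) and the stricter filter (-0.202). MYC (245 ± 1.25 and 253 ± 5.2, limma adjusted p = 0.335) and the myeloid factor SPI1 (13.5 ± 0.676 and 15.5 ± 0.0735, limma adjusted p = 0.0957) did not pass.

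Markers of other lineages were measured in small numbers. 4 of 12 megakaryocyte and platelet genes rose (5 adjusted over the list alone) and 0 fell: GP1BB (0.28), THBS1 (0.61), TUBB1 (0.42) and P2RY1 (0.21), and the list was not called (camera adjusted p = 0.186). GP1BB stood at -0.02 with the GC trend removed. The call of TUBB1 was lost without knockout replicate 2 (limma adjusted p = 0.189) and with thinned reads (limma adjusted p = 0.0976). That of P2RY1 was lost without control replicate 1 (limma adjusted p = 0.0799) or knockout replicate 2 (limma adjusted p = 0.15) and under library totals (limma adjusted p = 0.116) and quantile normalization (limma adjusted p = 0.051). Of 11 myeloid genes 1 rose (0 adjusted over the list alone), CEBPB by 0.18 (camera adjusted p = 0.772 for the list). Its call was lost without control replicate 1 (0.116) or either knockout library and under the 3 other scalings, and its sign turned with the trend removed (-0.065). The myeloid genes CEBPD (8.1 ± 0.466 and 9.9 ± 1.3, limma adjusted p = 0.0737) and CD68 (28.3 ± 1.2 and 26.8 ± 1.42, limma adjusted p = 0.403) did not pass. CEBPD passed upward without knockout replicate 2 (0.378), and CD68 passed downward with the trend removed (-0.187). Of 5 lymphoid genes 0 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.772). The T cell gene CD3D stood at 37.0 ± 0.571 and 34.2 ± 0.339 and passed downward under library totals (-0.186) and with the trend removed (-0.166). CD7 (1.81 ± 0.203 and 2.44 ± 0.24), RAG1 (5.35 ± 0.849 and 5.96 ± 0.105) and CD3G (1.75 ± 0.299 and 1.54 ± 0.431) did not pass. Of fibroblast, epithelial and endothelial genes 4 were measured, too few for the list test. The collagens COL1A1 (9.78 ± 0.907 to 15.3 ± 0.0424), COL6A1 (3.91 ± 0.241 to 6.45 ± 0.122) and COL3A1 (1.28 ± 0.552 to 2.91 ± 0.514) rose, over all genes and adjusted over the list alone. The epithelial gene EPCAM was 65.9 ± 0.151 and 67.9 ± 2.16.

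Genes of hypoxia and glycolysis formed another group that rose. 21 of 25 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 5.82e-14 and adjusted p = 0.406 with an estimated correlation). The glycolytic enzymes ALDOA and ALDOC rose from 2870 ± 118 to 4240 ± 66.3 (0.56, SE 0.04, limma adjusted p = 1.1e-08) and from 202 ± 1.16 to 276 ± 0.889 (0.45, SE 0.03), GPI rose by 0.42 (SE 0.04), and the angiogenic factor VEGFA from 417 ± 12.3 to 550 ± 2.78 (0.40, SE 0.03, limma adjusted p = 1.32e-07). Of 16 replication-dependent histone genes 10 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 9.75e-07 and adjusted p = 0.391 with an estimated correlation). Outside this list the histone gene HIST2H4B fell (-0.92, SE 0.14). On the list HIST1H2BJ rose by 0.54 (SE 0.05), HIST1H3H by 0.51, HIST1H2BK by 0.38 (SE 0.04) and HIST1H1C by 0.31 (SE 0.03). By contrast, 5 of 29 mitosis genes rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.523). With the GC trend removed 5 rose and 1 fell. Of the DNA replication genes 4 of 34 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.309), and with the GC trend removed 0 rose and 6 fell. Quantile normalization called both lists down (camera adjusted p = 0.0319 and 0.00848) and library totals the replication list (camera adjusted p = 0.0249). The mitotic genes CDC20, PLK1, BUB1, KIF20A and AURKB and the replication genes CDT1, MCM2, MCM5 and MCM7 rose, and PRIM1 (67.7 ± 2.72 to 55.1 ± 2.16), GINS4 and POLA1 fell. With the GC trend removed the calls of CDC20, PLK1, HMMR, AURKB, CDT1, MCM2, MCM5 and MCM7 were among those lost. Most of the 7 mitotic falls lost their calls as well. The call of BUB1 was lost under library totals (limma adjusted p = 0.0648) and quantile normalization (limma adjusted p = 0.0834).

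Lists of ribosome production and mitochondrial respiration held many small changes. Of 57 cytosolic ribosomal protein genes 29 rose and 0 fell (32 and 0 adjusted over the list alone), with a median of 0.1 (camera adjusted p = 3.13e-08 and adjusted p = 0.628 with an estimated correlation). Quantile normalization instead gave 15 rises and 17 falls and no call (median -0.008, camera adjusted p = 0.828). RPS19 rose from 942 ± 45.3 to 1140 ± 18.9 (0.27, SE 0.04). RPL13 rose from 2310 ± 10.2 to 2740 ± 58 (0.25, SE 0.03). Of 30 MYC targets and ribosome biogenesis genes 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 8.04e-05 and adjusted p = 0.391 with an estimated correlation). The spermidine synthase SRM rose by 0.54 (SE 0.05) and the ribosome assembly factors BOP1 and PES1 by 0.43 and 0.36 (SE 0.05 each), and the nucleolar MYBBP1A by 0.33 (SE 0.05). Of 43 measured entries for nuclear oxidative phosphorylation genes 21 rose and 1, NDUFB5, fell (24 and 1 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.000822 and adjusted p = 0.628 with an estimated correlation). Library totals gave 9 rises and 7 falls, and quantile normalization 9 and 5 without a call (median 0.01, camera adjusted p = 0.306). The respiratory chain subunits UQCRC1, NDUFS7, NDUFV1 and CYC1 rose by 0.29, 0.33, 0.27 and 0.28, and the calls of CYC1 (limma adjusted p = 0.201) and NDUFB5 (limma adjusted p = 0.205) were lost with the trend removed. Of 15 mitochondrially encoded genes 0 rose and 2 fell, also adjusted over the list alone: MT-ATP8 (426 ± 54.0 to 341 ± 5.95) and MT-ATP6 (3450 ± 0.0488 to 3200 ± 58.9). The change of MT-ATP8 went from -0.32 to -0.19 without control replicate 1, and the call of MT-ATP6 was lost without any 1 of the 4 libraries (limma adjusted p of 0.0698 to 0.24) and with the trend removed (limma adjusted p = 0.0883). The ribosomal RNA MT-RNR1 (958 ± 87.3 and 1040 ± 36, limma adjusted p = 0.0558) and the oxidase subunit MT-CO3 (4400 ± 87.9 and 4130 ± 67.4, limma adjusted p = 0.0667) did not pass. MT-RNR1 passed upward with the trend removed (0.133), the replicate block, the stricter filter, thinned reads and group weights, and without control replicate 1 or knockout replicate 2. MT-CO3 passed downward with the replicate block (-0.093) and under library totals (-0.171), median-of-ratios scaling (-0.12) and quantile normalization (-0.196). The list itself was not called (camera adjusted p = 0.129). It was called down under median-of-ratios scaling (camera adjusted p = 0.0328), library totals (camera adjusted p = 0.00137) and quantile normalization (camera adjusted p = 8.82e-05).

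Of 25 cholesterol synthesis genes 10 rose and 0 fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.00419 and adjusted p = 0.628 with an estimated correlation). The sterol enzymes EBP, DHCR7 and MVD rose by 0.34, 0.28 and 0.25, and the call of MVD was lost with the trend removed (0.04, limma adjusted p = 0.558). The list's call was lost without knockout replicate 2 (camera adjusted p = 0.12) and under quantile normalization (camera adjusted p = 0.0643), and its median was -0.01 under library totals. Of 31 autophagy and lysosome genes 9 rose and 1, CTSL, fell, also adjusted over the list alone (median 0.07, camera adjusted p = 0.0392 and adjusted p = 0.586 with an estimated correlation). This call was lost without control replicate 2 (camera adjusted p = 0.0671) or knockout replicate 2 (camera adjusted p = 0.12), with the replicate block (camera adjusted p = 0.0678), the stricter filter (camera adjusted p = 0.0946), thinned reads (camera adjusted p = 0.0725) and the GC trend removed (median 0.06, camera adjusted p = 0.101), and under median-of-ratios scaling (camera adjusted p = 0.0591), library totals (median -0.01, camera adjusted p = 0.116) and quantile normalization (camera adjusted p = 0.12). The lysosomal protease CTSD rose from 108 ± 0.951 to 140 ± 2.59 (0.37, SE 0.04) and the lysosomal membrane protein LAMP1 from 56.2 ± 1.22 to 68.7 ± 1.9 (0.28, SE 0.05). The autophagy protein ATG9A rose by 0.30 (SE 0.05) and the proton pump subunit ATP6V0D1 by 0.27 (SE 0.04).

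Stress and signalling lists went both ways. Of 23 genes of the unfolded protein and integrated stress responses 7 rose and 6 fell (8 and 6 adjusted over the list alone, camera adjusted p = 0.56). The list was called down without knockout replicate 1 (camera adjusted p = 0.0292), and with the trend removed 2 rose and 7 fell. The endoplasmic reticulum chaperone HSPA5 rose from 2390 ± 59.1 to 3150 ± 44.8 (0.40, SE 0.04, limma adjusted p = 2.87e-07) and HERPUD1 by 0.36 (SE 0.04). PSAT1, of serine synthesis, fell from 292 ± 2.75 to 210 ± 12.7 (-0.48, SE 0.04, limma adjusted p = 1.13e-07) and asparagine synthetase ASNS from 1020 ± 8.75 to 764 ± 67.9 (-0.42, SE 0.04, limma adjusted p = 1.48e-06). Of 22 p53 targets 5 rose (GDF15, BBC3, GADD45A, AEN and SESN2) and 3 fell (PMAIP1, DDB2 and XPC), 7 and 3 adjusted over the list alone (camera adjusted p = 0.409). The calls of BBC3 and SESN2 were lost with the trend removed. GDF15, a stress cytokine, rose from 368 ± 8.36 to 499 ± 2.62 (0.44, SE 0.03, limma adjusted p = 3.2e-08). Of 23 immediate early and MAPK feedback genes 4 rose (JUND, ETV4, JUNB and NR4A1) and 3 fell (FOSB, EGR1 and FOS), 6 and 3 adjusted over the list alone (camera adjusted p = 0.838). With the GC trend removed 1 rose and 5 fell, the calls of JUND, ETV4, JUNB and NR4A1 were lost, and the list was called down (camera adjusted p = 0.0264). FOSB fell from 30.6 ± 3.76 to 19.3 ± 1.6 (-0.64, SE 0.08, limma adjusted p = 1.18e-05) and EGR1 from 158 ± 8.19 to 121 ± 15.7 (-0.39, SE 0.06), or -0.258 without knockout replicate 1. The call of ETV4 was lost without knockout replicate 1 (limma adjusted p = 0.107) and under library totals and quantile normalization, and with the trend removed it stood at -0.02.

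Among 14 NF-kB and inflammatory genes 1, TNFAIP2, rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.409). The chemokines IL8 and CXCL3 fell from 13.8 ± 0.57 to 8.19 ± 0.0785 (-0.68, SE 0.09, limma adjusted p = 1.89e-05) and from 3.36 ± 0.0283 to 1.75 ± 0.185 (-0.67, SE 0.14), and IL6 from 2.78 ± 0.163 to 1.92 ± 0.0919, a call lost without any 1 of the 4 libraries. With the trend removed the calls of TNFAIP2 (from 0.29 to 0.10) and of IL6 (from -0.38 to -0.35) were lost. That of IL6 was also lost with the replicate block, no filter, a pseudocount of 0.1, quantile normalization and thinned reads (limma adjusted p of 0.054 to 0.195). Of 19 interferon response genes 7 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.409), and with the GC trend removed 1 rose and 2 fell. IFITM1 rose by 0.24 (SE 0.04), ISG15 by 0.29 (SE 0.06), TAP1 by 0.27 (SE 0.06) and IRF7 by 0.44 (SE 0.12). The calls of ISG15, TAP1 and IRF7 were lost with the trend removed, that of IRF7 also without knockout replicate 1 (limma adjusted p = 0.136). The call of IFITM1 was lost under quantile normalization (limma adjusted p = 0.0618). Of 25 apoptosis regulators 5 rose (BBC3, BAK1, BCL2L1, BID and BAD) and 6 fell (6 and 6 adjusted over the list alone, camera adjusted p = 0.507), among the latter CFLAR and PMAIP1 (-0.27 and -0.28, SE 0.05 each). The call of BAK1 was lost without knockout replicate 2 (limma adjusted p = 0.0692). With the trend removed 0 rose and 4 fell, so the calls of all 5 rises were lost. Of 26 PP2A subunits and regulators 6 rose and 3 (PPP2R5C, FAM122B and MASTL) fell, also adjusted over the list alone (camera adjusted p = 0.772). The scaffold subunit PPP2R1A rose from 212 ± 1.79 to 259 ± 5.59 (0.29, SE 0.03, limma adjusted p = 6.9e-06), as did the regulatory subunits PPP2R5B (0.34, SE 0.06) and PPP2R5D (0.21, SE 0.04). With the trend removed 4 genes of this list rose and 2 fell. The calls of PPP2R5B and MASTL were among those lost (limma adjusted p = 0.102 and 0.0728). The regulatory subunit PPP2R2A was 44.8 ± 0.123 in control and 43.9 ± 0.334 in knockout libraries (-0.03, SE 0.05, limma adjusted p = 0.733).

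**Figure D2:**
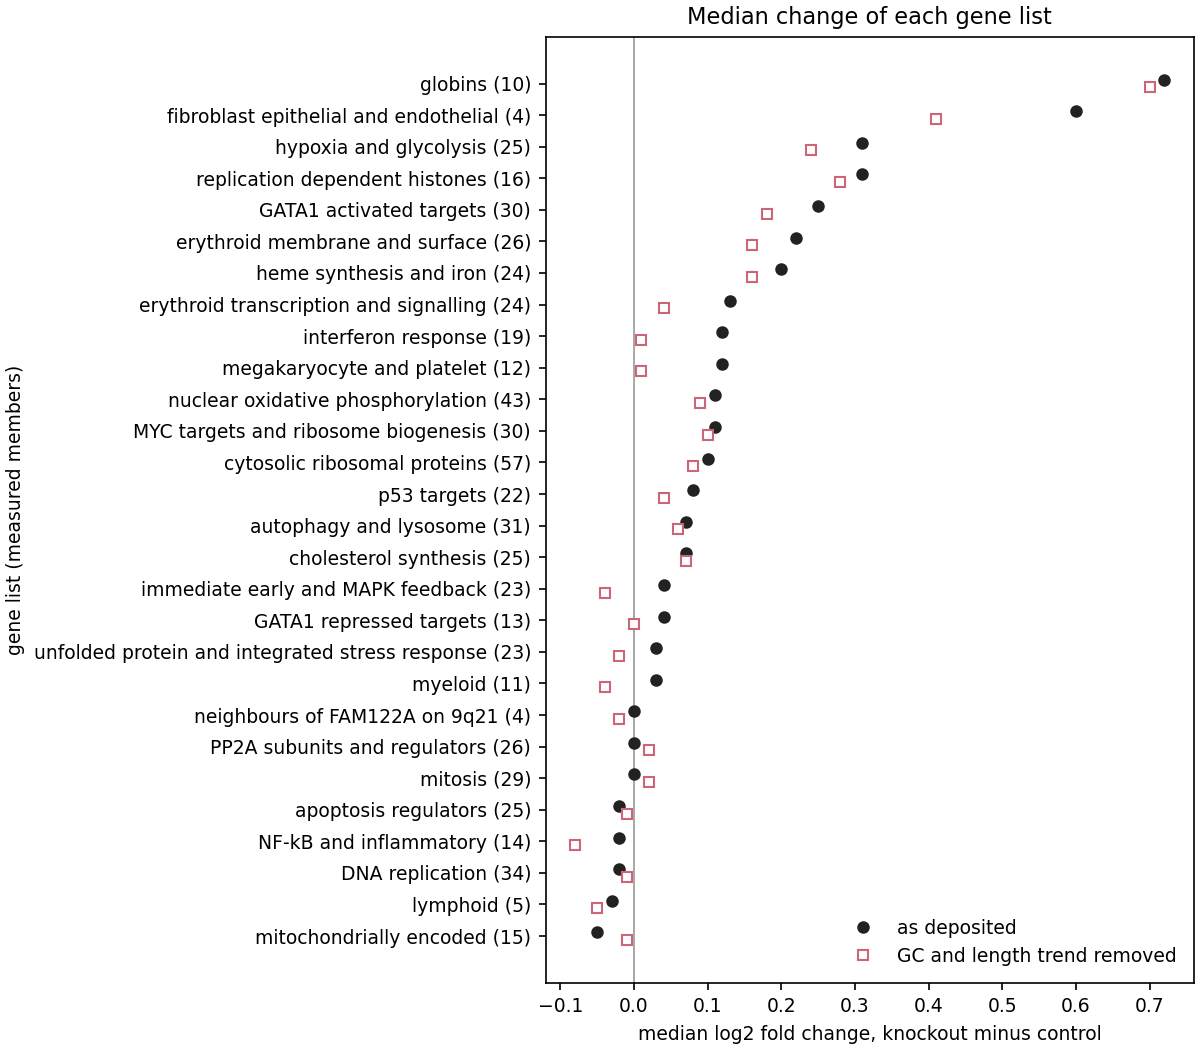
Median log2 fold change (knockout minus control) of the 28 gene lists, with the number of measured members in brackets; filled points are the values as deposited and open squares the values with each library's GC and length trend removed. The globin list moved from 0.72 to 0.7 and the erythroid transcription list from 0.13 to 0.04; the median of the ribosomal protein list falls below 0 under quantile normalization, and those of the cholesterol and autophagy lists under library totals.

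Outside the lists, further genes with large rises were the imprinted RNA H19 (33.4 ± 2.41 to 81.7 ± 4.86; 1.27, SE 0.06, limma adjusted p = 2.45e-11), C9orf135 (2.85 ± 0.344 to 9.53 ± 0.677; 1.45, SE 0.12) and CLCA1 (4.3 ± 0.457 to 10.6 ± 2.3; 1.11, SE 0.13). RN7SL1 (5.19 ± 0.794 to 15.6 ± 1.12) and SLX1B (2.77 ± 3.24 to 11.1 ± 2.78) have near-identical copies, and how shared reads were counted is not given in the sources used here. The rise of SLX1B, 2.00, was 0.978 without control replicate 2 and 3.02 without control replicate 1. Among genes with a mean of at least 5 that the naming rule takes, the largest falls were in the long noncoding RNA LINC00261 (12.5 ± 1.24 to 4.42 ± 0.612; -1.32, SE 0.11, limma adjusted p = 1.71e-07), and ASS1, argininosuccinate synthase (30.4 ± 3.8 to 15.5 ± 1.98; -0.93, SE 0.09, limma adjusted p = 7.48e-07). Large falls were also seen in HIST2H4B (-0.92, SE 0.14), MSH5-SAPCD1 (-0.90, SE 0.23), S100P (-0.76, SE 0.11), FAM19A2 and DLGAP1-AS2 (-0.69 each), PSMD5-AS1 (-0.66) and CYP2R1, a vitamin D hydroxylase (-0.64). MSH5-SAPCD1 overlaps other genes, its call was lost without control replicate 1 (limma adjusted p = 0.0756) or control replicate 2 (limma adjusted p = 0.0785), and its change was -1.57 without knockout replicate 1 and -0.24 without knockout replicate 2. The activation marker CD69 fell from 100.2 ± 0.385 to 66.3 ± 0.768 (-0.59, SE 0.04, limma adjusted p = 1.65e-08) and ACSM3, a fatty acid enzyme, from 292 ± 1.37 to 204 ± 6.9 (-0.51, SE 0.04, limma adjusted p = 1.19e-08). The immunoglobulin constant gene IGHM stood at 5.21 and 4.87 in the control libraries and at 0.057 and 0.083 in the knockout libraries (limma adjusted p = 2.4e-09). MSANTD3-TMEFF1, a readthrough gene model, stood at 5.75 and 4.81 in the control libraries and was listed at 0 in both knockout libraries.

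Over all 13249 genes tested 3924 (29.6%) changed, of which 2659 rose and 1265 fell (limma, Benjamini-Hochberg adjusted). Most of these changes were small: the median size was 0.24, 133 rose and 119 fell by at least 0.5, and 21 rose and 7 fell by at least 1. The split by direction depended on the scaling. The share of changed genes that rose was 67.8% with the deposited scaling, 57.1% under median-of-ratios scaling, 50.9% under quantile normalization and 36.5% under library totals. Fold changes also rose with GC content across genes (Spearman's rho 0.55; genes are not independent replicates). Among the 1288 genes with the lowest GC content 23 rose and 320 fell, and among those with the highest (61.6% to 76.8%) 682 rose and 13 fell. Within the control and the knockout group the difference between replicates had a rho with GC content of -0.18 and 0.13. With each library's trend removed 2203 genes changed (1262 rose, 941 fell), and 1661 of 3840 called genes with a known GC content (43.3%) passed again in the same direction. The removal also centres each library. With library medians kept 2529 genes changed, of which 70.2% rose.

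Beside this trend, 8 of 10 globins rose and 0 fell with the trend removed (median 0.7, camera adjusted p = 4.35e-17), as did 15 of 24 haem and iron genes (0.16), 15 of 26 membrane genes (0.16), 19 of 30 GATA1 activated genes (0.18), 20 of 25 hypoxia and glycolysis genes (0.24) and 9 of 12 histone genes with a known GC content (0.28), with 0 falls in each. The ribosomal protein list gave 23 rises and 1 fall (0.08), the MYC list 10 and 0 (0.1), the respiration list 17 and 0 (0.09), and the cholesterol list 7 and 1 (0.07). Of the 26 lists tested 12 were called, all up, and with the trend removed 11 were called, 10 up and 1 down. No list was called with an estimated correlation, and fry, which does not compare a list with other genes, called 10 in a single direction and 25 in either.

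**Figure D3:**
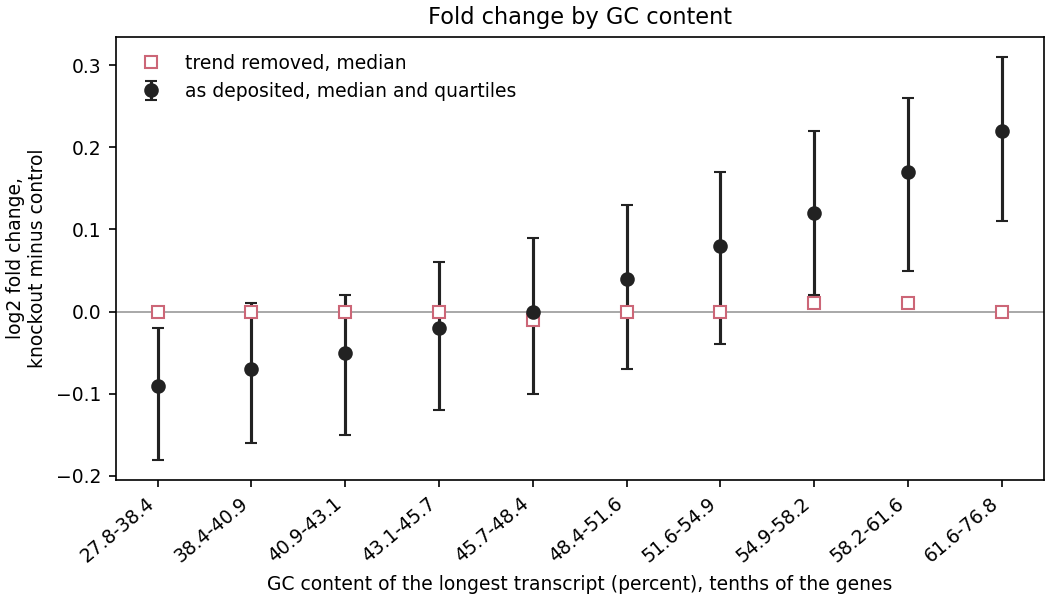
Log2 fold change (knockout minus control) of genes in 10 equal bins of GC content of their longest transcript, in percent; filled points and bars are the median and quartiles as deposited, open squares the median with each library's trend removed. The median rises from -0.09 in the lowest bin to 0.22 in the highest.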

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

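The thinning of reads, the removal of the GC and length trend (also with a size threshold or with library medians kept) and the group weights were chosen after seeing the data; the other settings were planned. The planned DESeq2, edgeR exact and limma-voom tests were not run: they were planned for deposited counts, and the reads inferred from the steps of the scaled values were not taken as counts for a test. The number of genes changed, 3924, stayed within 1.5 times under other scalings, filters and pseudocounts, with thinned knockout reads (3281 to 3561 in 10 draws) and with group weights. It was 2203 with the GC and length trend removed, 2529 with library medians also kept, 2446 at an adjusted p under 0.01, 28 with an absolute log2 change of at least 1, and 168 with the trend removed and at least 0.5; the 2 thresholds are stricter by construction. The share that rose, 67.8%, was 57.1% under median-of-ratios scaling, 36.5% under library totals, 50.9% under quantile normalization, 69.4% with thinned reads, 57.3% with the trend removed, which centres each library, 70.2% with library medians kept, 74% at an adjusted p under 0.01, 75% with a change of at least 1 and 33.9% with the trend removed and at least 0.5. Leaving out each library in turn, where the lone library of a group is assumed to vary like the other group, gave 2764 to 3273 genes, a share of 69.0% to 71.6%, 10 to 13 lists and a FAM122A change of -0.051 to 0.138. The number of lists called, 12, was 0 with an estimated correlation and 10 to 13 under the other settings. The estimated correlation is taken within each list from these 4 libraries. It was -0.08 to -0.01 for the globin, haem, membrane, erythroid transcription and GATA1 activated lists, below the preset 0.01. For the other called lists it was 0.04 to 0.46. A larger correlation was therefore not why the first-named lists lost their calls. With an estimated correlation the test rests on the 2 residual degrees of freedom, so it has little power here.

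FAM122A, which passed in none of these settings, lay at -0.028 under library totals. Also under library totals MYC lay at -0.032, EPCAM at -0.034 and PTAR1 at -0.007, and under quantile normalization the ribosomal protein list at -0.008, MYC at -0.032 and EPCAM at -0.004. With the trend removed MYC lay at -0.045, SPI1 at -0.041, PPP2R2A at 0.055, GP1BB at -0.023, CEBPB at -0.065, CEBPD at -0.028 and ETV4 at -0.02. CD3G ranged from -0.294 to 0.053 without single libraries. Of these genes only GP1BB, CEBPB and ETV4 had been called; the cause was not tested beyond the construction of each setting. Over the named genes and settings 1651 results were unchanged in direction and call, 54 lost the call, 21 gained it and 13 changed sign. For the lists 355 results were counted as unchanged, 25 lost the call, 8 gained it and 1 changed sign. A list called in neither setting was counted as unchanged even where its direction turned, as for the mitosis list with the trend removed. The replicate numbers did not pair the libraries (correlation of deviations -0.03): with the replicate block 4093 genes changed, 67.2% of them upward, and 11 lists were called, without the autophagy list.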

Other observations

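Families defined by the letters that open a gene symbol, and chromosome arms, were examined after seeing the data, with at least 10 members each. Of 142 families 8 were called (camera at the preset correlation), and 11 with the GC trend removed. Zinc finger genes of the ZNF family, mostly DNA-binding repressors, lay lower: 77 of 372 fell and 28 rose (median -0.11; camera, adjusted p = 0.000202), and with the trend removed 40 fell and 13 rose (camera, adjusted p = 0.0018). Translation factors of the EIF family had 22 rises and 4 falls among 54 genes (camera, adjusted p = 0.0981), and 18 and 1 with the trend removed (camera, adjusted p = 4.06e-05). No family was called with an estimated correlation (adjusted p = 0.937 for both), and no arm was (lowest adjusted p = 0.213). Of 41 arms 15 were called, and 0 with the trend removed. Arm 9q, which carries FAM122A, had 82 rises and 46 falls with a median of 0.01 (camera, adjusted p = 0.555), and 19 and 53 with the trend removed (median -0.03; camera, adjusted p = 0.265).

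The immunoglobulin genes IGKC and IGHG1 were looked at after their values were seen, because IGHM had fallen. IGKC stood at 1.72 and 1.19 in the control and 0.359 and 0.38 in the knockout libraries, and IGHG1 at 0.492 and 0.712 in the control and 1.28 and 1.77 in the knockout libraries.

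The tests below on near-identical globin copies, on MSANTD3-TMEFF1, on the share that rose under 3 other scalings and on trend removal with library medians kept were written after the results were seen; the others were written before. The first pattern is that more genes rose than fell, by small amounts. With the knockout reads thinned to the control depth, the rank correlation of fold change with GC content was 0.53 and 69.4% of the called genes rose. Thinning keeps the expected value of each gene, so fold changes were bound to stay near those of the main test. The result shows only that the number of sampled reads did not set the pattern. A difference that came with the deeper sequencing of the knockout libraries cannot be tested this way and stays open. The excess of rises depended on the scaling: 57.1% of the called genes rose under median-of-ratios scaling, 50.9% under quantile normalization and 36.5% under library totals. These shares do not tell which scaling is right. For the rise with GC content the test of the deposited scaling was void. Scaling to the median gene moves nearly all genes alike and left the rank correlation at 0.55. A GC and length trend that differs between libraries stays open. Without it 43.3% of the called genes passed again in the same direction, against 88.9% under median-of-ratios scaling. The share that rose was 57.3% when the removal centred each library and 70.2% when it kept each library's median. The share thus depended on the offset of each library, so it cannot decide whether the excess of rises went with the trend. The trend may be technical or an effect of the knockout on GC-rich genes.

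The second pattern is the rise of the globin genes. A median of 0.7 with the trend removed argues against the GC and length trend as the cause of this rise. The summed values argue against a shift of reads between near-identical copies: the smaller rise, that of HBG1 with HBG2, was 0.71. The median was 0.72 with thinned reads, but thinning keeps expected values, so it cannot decide on a difference in depth. The lowest median under the other scalings was 0.58. A hypothesis, not tested here, is that cells labelled FAM122A knockout moved further along the erythroid programme. Beside the globins 16 of 24 haem and 17 of 26 membrane genes rose and 0 fell. Library totals gave 13 rises and 1 fall in each of these lists. Quantile normalization gave 11 and 0 for haem and 14 and 2 for membrane genes. Both lists stayed called up under these scalings (highest camera adjusted p = 8.82e-05). However, the erythroid transcription list lost its call with the trend removed (median 0.04, camera adjusted p = 0.187). Genes listed as repressed by GATA1 did not move as a set (3 rose, 2 fell, camera adjusted p = 0.772), and EPOR did not pass. The globin, haem and membrane lists lost their calls with an estimated correlation (camera adjusted p = 0.187 each), as did every other called list. That test rests on 2 residual degrees of freedom and has little power, so this loss does not weigh against the hypothesis. A difference between cultures or clones that arose apart from the edit was not tested and may give the same pattern.

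The third pattern is the absence of MSANTD3-TMEFF1 from both knockout libraries. In GENCODE 29 this model shares exon bases with MSANTD3 and TMEFF1. The summed value of the 3 genes differed by -1.14 between the group means, less than the 2.8 between the control libraries, and TMEFF1 stood at 8.26 and 8.90 in the control and 11.6 and 11.4 in the knockout libraries. A candidate explanation is that its reads were counted to its overlapping genes instead. A loss of the readthrough transcript itself was not tested, and with a separate rise of TMEFF1 it could leave the same sum. Looked at after their values were seen, RP11-514P8 and AC009133 also stood at 0 in both knockout libraries. In the control libraries RP11-514P8 stood at 1.38 and 2.02 and AC009133 at 1.57 and 1.42. The cause was not tested.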
